A study of Arabidopsis thaliana with 10 samples.

How the data were processed

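A course of 10 samples of 1 Arabidopsis thaliana cell suspension culture was measured on 10 ATH1 arrays, 1 array for each sampling time of 0, 2, 4, 6, 8, 10, 12, 14, 16 and 19 h after release from an aphidicolin block. Per the labels' protocols, the RNA was total RNA, labelled with biotin. The deposited values are MAS5 signal values, an intensity per probe set on a linear scale, and the version of the MAS5 software was not given in the sources used here. That these values come from MAS5 was stated per the submitters' processing notes. The deposited intensity values had already been scaled by the authors, as the values themselves show: the 2% trimmed mean of each array, without control probe sets, lay between 99.3 and 99.4. MAS5 computes 1 value per probe set within each array, so no probe-level information was used here, and low values carry much noise.

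The table held 22810 probe sets, of which 64 were control probe sets and were left out of all tests. Gene names came from the platform annotation, with symbols updated from a RefSeq gene table of assembly TAIR10.1, which was used for names only. Of the remaining 22746 probe sets, 13513 named 1 gene, 503 named several genes and 8730 were listed without a gene. Of the probe sets with 1 gene, 13436 matched the gene table by Entrez gene ID, and 1580 had a symbol other than their locus code. No gene was named from a probe set with several genes, except that 2 probe sets naming only copies of a core histone were used and are described as such. Many well-known cell cycle genes had no probe set named in the annotation used, so they were not analysed here.

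Each array was rescaled to a 2% trimmed mean of 100. Values under the 25th percentile of all values, a signal of 12.1, were set to that value before log2 was taken. A difference against a time or window at this floor is therefore a lower bound. Probe sets were tested where their mean over the 10 arrays was above the 40th percentile of such means, which left 13647, of which 7672 named 1 gene, 1026 had a symbol and 5687 had no gene listed.

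With R 4.3.3 and limma 3.58.1, the time course was tested with a natural cubic spline of time with 4 degrees of freedom and the moderated F test. Window contrasts compared early (0, 2 and 4 h, 3 samples), middle (6, 8, 10 and 12 h, 4 samples) and late (14, 16 and 19 h, 3 samples) times in 1 limma fit. Both used eBayes with a mean trend and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called. Errors given as SE are those of the limma contrast. Samples of a window are different times and not replicates, and all came from 1 culture course, so p-values measure only the spread between these samples. Gene lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and the 3 contrasts. Camera sets the moderated statistics of members against those of the other tested probe sets. Its direction is therefore relative to these and is not an absolute rise or fall. The differences between 0 h and 2 h and between 16 h and 19 h had 1 array on each side and no test. There, a list's median was given as its percentile among 10000 random lists of the same size matched on mean signal. Random lists hold unrelated genes, so these percentiles do not allow for correlation between the genes of a list.

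The windows, tests, naming rule, lists and alternatives were fixed before the data were examined. Exceptions chosen later were 14 further lists, written from the gene names in the annotation before any gene's value was looked at, Fisher's exact test (two-sided) of list members called in the time course, and fits without the 0 h and 2 h arrays. These lists are called added lists. Fisher's exact test used the 7960 tested probe sets with a gene, of which 401 were called, and treats genes as independent, which genes of 1 process are not. Genes named in the text were the 10 largest rises and falls per window contrast among called probe sets with 1 gene, a symbol and windows apart in every sample, the 10 largest fitted ranges in the time course, and the 5 largest rises and falls per single interval. Members of lists could be named too, and where under 5 genes passed, those with the lowest p were named. Called members of the added lists, and genes that follow a mean course, were chosen after their values were seen.

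The tests were tested on simulated data with the spread of the real probe sets, in which 200 of 13647 probe sets were changed. For middle against early, 55% of simulated changes of 1 log2 unit and 97% of those of 2 units were recovered. These shares were 49% and 92% for late against middle and 48% and 90% for late against early, with 7 or 8 false calls in each. For the time course, none of the changes shaped as a bell peaking at 11 h were recovered, at 0% for both sizes, and why was not tested. With the shape of a spline term, added after that result, 34% and 81% were recovered. That shape had larger median fitted ranges, 1.39 and 2.67, against 1.05 and 1.94 for the bell. For late against early, camera was tested on 40 simulated lists of 7 members and called 10 of 10 moved lists and 0 of the unmoved ones. Genes varied independently in this simulation, while the estimated correlation was 0.70 for core histones and 0.56 for G2 and mitosis. It therefore does not show how often camera calls unmoved lists of correlated genes.

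Alternatives covered the floor, the filter, the scaling, the moderation, the spline, the window borders, the correlation in camera and leaving out each array in turn. The number of arrays limits the precision of all results.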

Results

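Transcript levels were measured across the release of Arabidopsis MM2d cells from a block of DNA replication. MM2d is a fast-dividing suspension line grown in the dark, and aphidicolin inhibits replicative DNA polymerases, so that cells are held around the start of S phase. Early stationary cells were diluted into fresh medium with aphidicolin for 24 h, washed through a nylon net and spun gently to remove the drug. The 0 h sample was taken directly after this wash. Each of the 10 times had 1 array and no replicate, so scatter was judged from a smooth curve or from neighbouring times. The arrays had median signals between 35.0 and 43.6 and 23.2% to 26.9% of probe sets at the floor. The series title gives genome-wide study of the cell cycle as its purpose.

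Over the whole time course, several of the genes with the largest fitted ranges were lowest in the first hours and highest at 10 or 12 h. The signal of 3xHMG-box2, an HMG-box protein of plant chromosomes, was at the floor from 0 h to 4 h and reached 518 at 10 h, an observed range of at least 5.42 log2 units (adjusted p = 0.00134). KINESIN-12B, a phragmoplast kinesin, was at the floor over the same times and reached 97.0 at 10 h, an observed range of at least 3.00 (adjusted p = 0.00237). TOPII, topoisomerase II, went from 57.8 at 0 h to 751 at 10 h, and UBC20, a ubiquitin-conjugating enzyme, from 180.3 at 0 h to 1208 at 12 h, with fitted ranges of 3.39 and 3.54. Other genes were highest at 0 h or 2 h: ZCF37 stood at 600.1 at 0 h and 43.0 at 4 h, with an observed range of at least 5.63. CML23, a calmodulin-like protein, stood at 172 at 0 h and at the floor at 4 h and 6 h, a range of at least 3.83. It was higher again later, with 43.2 at 8 h and 48.7 at 19 h. CHI, a chitinase, was highest at 2 h with 812 and stood at 44.3 at 14 h, with a fitted range of 3.99. ZCF125 and ATLP-1, a thaumatin-like protein, had fitted ranges of 3.42 and 3.14, and BUBR1, a spindle checkpoint protein, which was at the floor at 6 h, an observed range of at least 3.05.

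In all, 760 of 13647 probe sets were called in the time course (limma F test), against 3390 at an unadjusted p under 0.05. Of the 760, 74 had a symbol and 359 no gene listed. They were highest in the early window in 330 cases, in the middle window in 264 and in the late window in 166, with 195 highest at 0 h, 124 at 10 h and 97 at 19 h. The fitted range was over 1 log2 unit in 629 and over 2 in 279, with a median of 1.64. Calls for 3xHMG-box2, CHI, UBC20, ZCF125, ATLP-1 and KINESIN-12B passed in every alternative run for them. ZCF37 was lost without the 0 h array (adjusted p = 0.0839), without the filter (0.105) and without both the 0 h and 2 h arrays (0.524; 0.00635 to 0.524 over its alternatives). Its fitted range was 5.23, 2.79 without the 0 h array and 1.68 without the 0 h and 2 h arrays. CML23 was lost without the 0, 4 or 6 h array (0.0531 to 0.166), without the filter (0.0726), with 3 spline terms (0.143) and without the 0 h and 2 h arrays (0.0832; 0.0108 to 0.166 over its alternatives). Its fitted range was 3.81, 1.87 without the 0 h array and 2.29 without the 0 h and 2 h arrays. BUBR1 was lost without the 10, 12, 14 or 16 h array (0.0605 to 0.0783), without a floor (0.0503) and without the filter (0.0872; 0.00198 to 0.0872 over its alternatives). TOPII was lost without any 1 of the arrays from 4 h on (0.0631 to 0.132), without the filter (0.162), without a mean trend (0.0687) and with 3 or 5 spline terms (0.0734 and 0.0820; 0.000227 to 0.162 over its alternatives). The count of 760 moved by over 1.5 times whichever array was left out: to 2901 without 0 h, 1844 without 2 h, 323 without 4 h, 492 without 6 h, 318 without 8 h, 401 without 10 h, 236 without 12 h, 304 without 14 h, 335 without 16 h and 398 without 19 h. It was 281 without the filter and 462 without a mean trend. Without both the 0 h and 2 h arrays, a setting chosen after seeing the data, it was 1231, of which 484 were among the 760.

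All 7 tested genes of the G2 and mitosis list, fixed beforehand, changed over the time course, and 7 did adjusted over the list alone. Of these, 6 were highest at 10 h: the Aurora kinases AUR1, AUR2 and AUR3, BUBR1, KINESIN-12B and AT4G14330. AUR1 stood at 76.2 at 4 h, 555 at 10 h and 203 at 19 h, with a fitted range of 2.80 (adjusted p = 0.000320). AUR2 went from 26.1 at 4 h to 102.5 at 10 h, and AUR3 from 86.8 at 0 h to 213 at 10 h and 79.7 at 16 h. The exception was HTR12, the centromeric histone H3 variant, which was highest at 2 h with 93.9 and lowest at 19 h with 29.4 (adjusted p = 0.0345). Fisher's exact test set the 7 of 7 against 5.04% of all tested probe sets with a gene (adjusted p = 1.41e-08), and the list passed in each of its 20 alternatives (adjusted p 3.32e-10 to 0.00305, with 3 to 7 members called). The fewest members, 3, were called without the 12 h or the 14 h array, and 4 without the 10 h array or without the filter. The list named 40 genes, and the B-type cyclins and CDKB kinases among them were not analysed here.

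**Figure D1:**
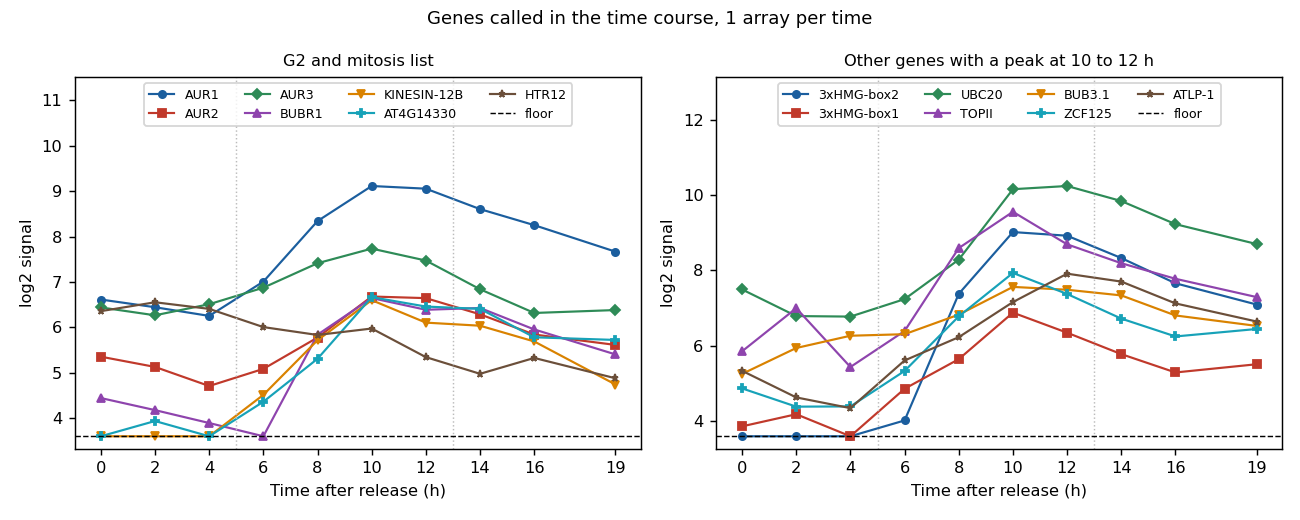
Log2 signal against time after release (h), 1 array per time, for the 7 members of the G2 and mitosis list on the left and 7 other called genes on the right, with window borders dotted and the floor dashed. AUR1 rises from 76.2 at 4 h to 555 at 10 h in linear signal, while HTR12 is highest at 2 h.

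An added list of 15 tested genes of mitosis and cytokinesis held 4 that were called: BUB3.1, TOPII, 3xHMG-box1 and 3xHMG-box2 (Fisher's exact test, adjusted p = 0.0306; 0.0245 to 0.719 over alternatives). BUB3.1, a spindle checkpoint protein, went from 38.1 at 0 h to 189 at 10 h, and 3xHMG-box1 from the floor at 4 h to 118 at 10 h. The other 11 members were not called. The list's call was lost without the 0, 2, 10, 12, 14 or 19 h array (adjusted p 0.0511 to 0.570), without the filter (0.719), with the 60th percentile filter (0.198), without a mean trend (0.0728), with 3 or 5 spline terms (0.146 and 0.0696) and without the 0 h and 2 h arrays (0.134). Of 7 tubulins, TUA6 was called, with 1350.1 at 4 h and 2508 at 12 h (Fisher's exact test, adjusted p = 0.607).

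Core histone transcripts were highest in the early window for 5 of 6 probe sets, each of these at 2 h, the time of the array with the lowest mean correlation with the others (0.864). A probe set shared by 8 histone H4 genes went from 3727 at 2 h to 1460.2 at 14 h, and HTB1, a histone H2B, from 391 at 2 h to 183 at 12 h. The probe set shared by 5 histone H3 genes was highest at 8 h with 3722 and stood at 2007 at 14 h. These 3 of 6 tested members were called in the time course (adjusted p = 0.02498, 0.0175 and 0.02498), and 6 were called adjusted over the list alone. HTB2, HTB4 and HTB11 had fitted ranges of 1.52, 1.25 and 1.96 and were not called over all genes. Fisher's exact test gave the list an adjusted p = 0.0204 (8.09e-07 to 1 over alternatives). This was lost without the 4, 8, 10, 12, 14, 16 or 19 h array (0.0770 to 1), without the filter (1), with the 60th percentile filter (0.0517), without a mean trend (0.425) and with 5 spline terms (0.0696).

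**Figure D2:**
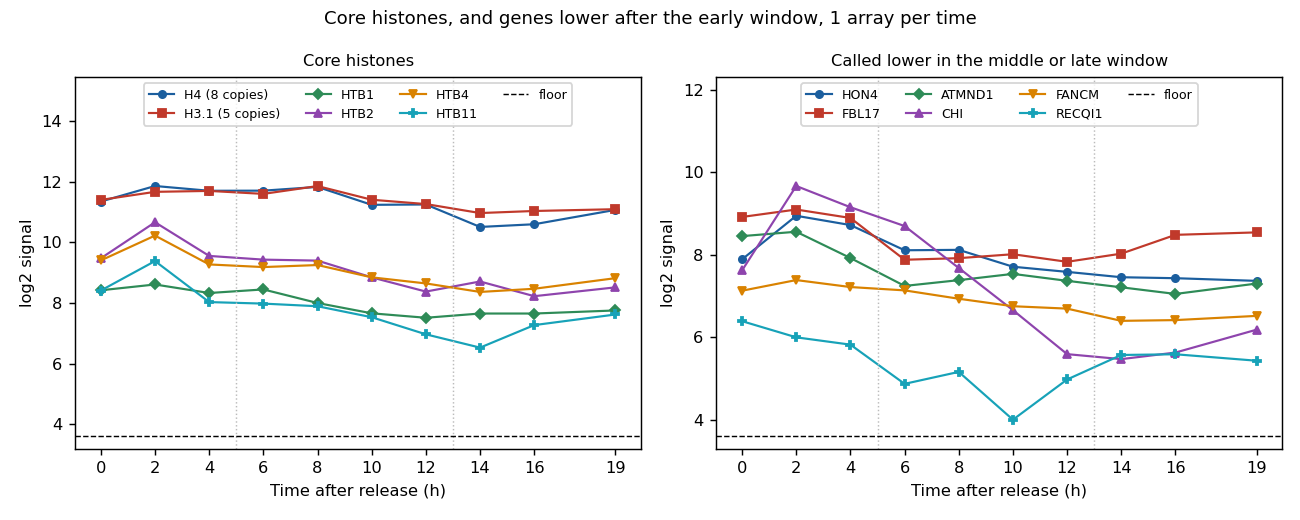
Log2 signal against time after release (h), 1 array per time, for the 6 core histone probe sets on the left and 6 genes called lower in the middle or late window on the right, with window borders dotted and the floor dashed. HTB2 stands at 1625.5 at 2 h and 299 at 16 h in linear signal, and CHI at 812 and 49.5.

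Of the 23 photosynthesis markers fixed beforehand as a sign of leaf-like cells, 3 were tested. In the time course 2 of these 3 were called, RCA, rubisco activase, and LHCB4.1, an antenna protein, and 2 were called adjusted over the list alone. Both were lowest at 2 h, RCA with 105.5 against 299 at 8 h and LHCB4.1 with 49.6 against 131 at 19 h. Fisher's exact test gave the list an adjusted p = 0.0306 (0.0256 to 1 over alternatives). That was lost without any 1 array other than 0 h (0.0873 to 1), without the filter (1), with the 60th percentile filter (0.0770), without a mean trend (0.259), with 5 spline terms (0.281) and without the 0 h and 2 h arrays (0.368). Of 9 expansins and XTH wall enzymes (added list), EXPA15, EXPB3 and XTH20 were called, all 3 highest at 19 h (adjusted p = 0.0306; 8.65e-05 to 1 over alternatives). This was lost without the 4, 8, 10, 12, 14, 16 or 19 h array (0.101 to 0.764), without the filter (1) and without a mean trend (0.124).

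Of 3 tested touch and wounding genes, from a list of 21, WRKY53 was called, and 3 were called adjusted over the list alone. Fisher's exact test gave this list an adjusted p = 0.323, and it passed without the 2 h array (0.0120) and with 5 spline terms (0.02501; 0.0120 to 1 over alternatives). ATG8E, the single sugar starvation gene tested, went from 610.0 at 0 h to 152 at 16 h (adjusted p = 0.0192), and 1 was called adjusted over the list alone. Among the added lists, FANCM and UNG were called of 12 DNA repair genes (Fisher's exact test, adjusted p = 0.308), and rpoC1, petB, rpl22 and rpl32 of 68 plastid genome probe sets (adjusted p = 1). PSBY and PSAE-1 were called of 6 nuclear photosynthesis genes (adjusted p = 0.0995), a list that passed without the 6 h array (0.0492) and with 3 spline terms (0.0224; 0.0224 to 1 over alternatives). CML23 was called of 12 calcium and stress-induced regulators (adjusted p = 0.832), a list that passed without the 2 h array (0.0272, with 5 called; 0.0272 to 1 over alternatives).

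In limma, 0 members were called of 3 DNA replication genes (1 at an unadjusted p under 0.05 and 1 adjusted over the list alone) and of 3 reference genes (0 and 0). The DNA replication list named 29 genes, so most of them were not analysed here. Among the added lists, 0 members were called of 5 genes of replication and chromatin assembly (2 at an unadjusted p under 0.05), 11 UDP-glycosyltransferases (4), 9 autophagy genes of the ATG8 and ATG3 families (8), 10 RNA polymerase subunits (4) and 7 genes of the mitochondrial TCA cycle and succinate dehydrogenase (3). By Fisher's exact test these 7 lists had an adjusted p = 1, and the ATG8 and ATG3 list passed with 3 spline terms (0.0411; 0.0411 to 1 over alternatives). ATG8E, which was called, counted as the sugar starvation gene and was not a member of the ATG8 and ATG3 list. Lists with under 3 tested members had no list test. The 2 genes of the DNA damage response and the single genes of auxin response, primary cell wall and circadian clock had 0 called over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The 2 tau glutathione transferases and the single gene of dehydration and cold had 0 called and 0 at an unadjusted p under 0.05. The lists of other A-type cyclins, G1 control and ribosome and nucleolus had 0 probe sets named in the annotation used. The same held for proteasome core, secondary wall and seed storage, so these lists say nothing about expression. Heat shock, cytokinin response and xenobiotic response had 1, 2 and 1 named probe sets, of which 0 passed the filter on mean signal.

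The middle window (6 to 12 h) was compared with the early window (0 to 4 h) to ask what changed as cells moved on from the block. Transcripts of ZCF125 rose by 2.31 log2 units (SE 0.48, adjusted p = 0.0498) and those of 3xHMG-box1 by at least 2.05 (SE 0.40, adjusted p = 0.0425; at the floor at 4 h). PORB, which makes chlorophyllide, rose by 1.64, RCA by 1.07 (SE 0.16, adjusted p = 0.0177), FDH, formate dehydrogenase, by 1.44 and scpl50, a carboxypeptidase-like protein, by 1.48. COS1, a riboflavin pathway enzyme, rose by 0.70 and NDB4, a NAD(P)H dehydrogenase, by 0.67. FBL17, an F-box protein that targets inhibitors of cyclin-dependent kinases, fell by 1.06 (SE 0.14, adjusted p = 0.0137). RECQI1, a RecQ helicase, fell by 1.32, ATMND1, a homologue of a meiotic recombination factor, fell by 0.93, LigB fell by 0.92 and ACLA-1, a subunit of ATP citrate lyase, fell by 0.57.

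In limma 71 probe sets were higher and 83 lower, against 2959 at an unadjusted p under 0.05. The windows were apart in every sample for all 154, and over all probe sets in 16.1%. For independent samples chance gives 5.71%, but neighbouring times of 1 culture are alike, so the share expected by chance here is not known. The total of 154 became 496 without the 0 h array, 18 without 2 h, 1863 without 4 h, 334 without 6 h, 2 without 12 h, 59 without 14 h, 29 without 16 h and 42 without 19 h. It was 0 without 8 h (limma; 2555 at an unadjusted p under 0.05), 0 without 10 h (2386) and 0 without the filter (3287), 71 without a mean trend, 263 with the 60th percentile filter and 52 with 12 h moved to the late window. With 6 h moved to the early window, 115 were higher and 37 lower, 31 of them among the 154. Without the 0 h and 2 h arrays, chosen after seeing the data, 55 were higher and 37 lower, 13 of them among the 154. All 13 named calls were lost without the 8, 10 or 12 h array, 11 without 2 h, 10 without 14 h, 10 without 16 h, 9 without 19 h, 1 without 0 h (RECQI1) and 1 without 6 h (ACLA-1), with an adjusted p of 0.0502 to 0.136. All 13 were also lost without the filter (0.0645 to 0.138) and without the 0 h and 2 h arrays (0.0508 to 0.294), 11 with 6 h moved to the early window (0.0732 to 0.367), 10 with 12 h moved (0.0532 to 0.0963) and 9 without a mean trend (0.0596 to 0.0789). A pseudocount ended 3 (0.0516 to 0.0591), no floor 2 (0.0504 to 0.0523), quantile normalization 2 (0.0538 to 0.0579), median centring 2 (0.0508 to 0.0511) and robust moderation 1 (0.0586). Differences were 0.73 for FDH, 0.70 for RCA and -0.54 for ATMND1 without the 0 h and 2 h arrays, and -0.61 for ATMND1 with 6 h moved. Of the early arrays, those at 0 h and 2 h had the lowest mean correlations with the other arrays, 0.912 and 0.864.

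As a group, the 7 genes of the G2 and mitosis list were higher in the middle window, with 6 of 7 positive and a median difference of 1.45 (camera, adjusted p = 0.00637; adjusted p = 0.458 with an estimated correlation). In limma 0 passed over all genes (7 at an unadjusted p under 0.05) and 7 adjusted over the list alone, 6 up and HTR12 down. The list's call was lost without the 4 h array (adjusted p = 0.0747; 1.78e-07 to 0.458 over alternatives), and its median was 2.26 with 6 h moved to the early window. Core histones were lower, with 0 of 6 positive and a median of -0.60 (adjusted p = 0.00548; adjusted p = 0.458 with an estimated correlation), 0 over all genes (4 at an unadjusted p under 0.05) and 4 adjusted over the list alone. Without the 0 h and 2 h arrays the histones' median was -0.36 (adjusted p = 0.0893; 0.000310 to 0.458 over alternatives). Photosynthesis markers were higher, with a median of 0.88 and 3 of 3 positive (adjusted p = 0.00319; adjusted p = 0.351 with an estimated correlation), 1 over all genes and 3 adjusted over the list alone. Their median was 0.59 without the filter and 0.39 without the 0 h and 2 h arrays.

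Among the added lists, the 9 ATG8 and ATG3 genes were lower, with 0 of 9 positive and a median of -0.41 (adjusted p = 2.86e-05; adjusted p = 0.351 with an estimated correlation), or -0.27 without the 0 h and 2 h arrays. The 6 nuclear photosynthesis genes were higher, all positive, with a median of 0.71 and PORB called (adjusted p = 0.00548; adjusted p = 0.429 with an estimated correlation). Without the 0 h and 2 h arrays their median was 0.28 (0.359; 0.00120 to 0.429 over alternatives). The 12 calcium and stress-induced regulators were lower, with a median of -0.50 and 1 positive (adjusted p = 0.00319; adjusted p = 0.351 with an estimated correlation). Their median was -0.29 without the 2 h array (0.121), -0.08 without the 0 h and 2 h arrays (0.928; 0.000497 to 0.928 over alternatives) and -0.99 without 4 h. The 5 genes of replication and chromatin assembly were lower, with a median of -0.19 and FBL17 called (adjusted p = 0.0462; adjusted p = 0.351 with an estimated correlation). That was lost without the 0, 2, 4, 8, 10 or 12 h array (0.0521 to 0.132, medians -0.39 to -0.07), with quantile normalization (0.0616), with 12 h moved (0.0701) and without the 0 h and 2 h arrays (0.357, median -0.01; 0.0240 to 0.357 over alternatives).

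No other list passed in this contrast. The 3 DNA replication genes had a median of -0.25 (adjusted p = 0.151), with 1 adjusted over the list alone, AT1G07270, a CDC6 homologue, at -1.20. Their median was -0.14 without the 2 h array. The 3 touch and wounding genes had a median of -0.68 (adjusted p = 0.1004), with 1 adjusted over the list alone, and passed without the 2, 4 or 12 h array (0.0421 to 0.0474) and with 12 h moved (0.0484; 0.0421 to 0.565 over alternatives). Their median was -1.28 without the 2 h array and -1.46 without 4 h. RNA polymerase subunits had a median of 0.20 (adjusted p = 0.124) and passed without the 4 h array (0.00600, median 0.36) and with quantile normalization (0.0436; 0.00600 to 0.679 over alternatives). Their median was 0.09 with 6 h moved and -0.10 without the 0 h and 2 h arrays. Mitosis and cytokinesis had 0.07 and passed with 6 h moved (0.0489; 0.0489 to 0.750), and expansins and XTH enzymes had 0.23 and passed without the 0 h and 2 h arrays (0.0495, median 0.53; 0.0495 to 0.907). Medians over the alternatives ran from -0.01 (quantile normalization) to 0.15 (without 12 h) for mitosis and cytokinesis and from -0.09 (without 2 h) to 0.68 (without 0 h) for the expansins and XTH enzymes. Other medians, with their range over alternatives in brackets, were 0.13 for tubulins (-0.03 to 0.22), 0.09 for UDP-glycosyltransferases (-0.06 to 0.40) and 0.04 for the mitochondrial list (0.0016 to 0.14). All tested probe sets had a median difference of 0.0738 in this contrast, and camera's direction is relative to the other probe sets. The reference genes (median 0.03, mean -0.01, with 0 adjusted over the list alone), DNA repair (0.10 and 0.01) and the plastid genome (0.09 and 0.02) had positive medians while camera's direction was down. Their medians ran from -0.22 to 0.07, from -0.09 to 0.14 and from -0.0004 to 0.11 over alternatives. In at least 1 alternative the median turned negative for the reference genes, mitosis and cytokinesis, DNA repair, tubulins, expansins and XTH enzymes, UDP-glycosyltransferases, RNA polymerase subunits and the plastid genome.

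The late window (14 to 19 h) was compared with the early window to see what differed between the ends of the course. GH9C2 and GH9B8, endoglucanase-like hydrolases, rose by 1.79 (SE 0.32, adjusted p = 0.0232) and 1.62, the expansins EXPB3 and EXPA15 by 1.69 and 1.64, TBL36, of a family of wall polysaccharide acetyltransferases, by 1.39, and XTH20, a xyloglucan-modifying enzyme, by 1.08 (SE 0.16, adjusted p = 0.0131). ATLP-1 rose by 2.39, PORB by 1.43, UNG, uracil DNA glycosylase, by 1.26 and DI21, a drought-induced protein, by 1.22. The histones HTB2 and HTB4 fell by 1.42 and fell by 1.08, HTR12 fell by 1.38 (SE 0.21, adjusted p = 0.0133) and HON4, a linker histone-like protein, fell (adjusted p = 0.0380). CHI fell by 3.05, and CYP71B5, a cytochrome P450, fell by 2.66, a lower bound since all 3 late arrays were at the floor. ATMND1 fell by 1.12, ATMAP65-6, a microtubule-associated protein, fell by 1.11, LigB fell by 0.86 and FANCM, a DNA repair helicase, fell by 0.80.

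Here 309 probe sets were higher and 245 lower in limma, against 3230 at an unadjusted p under 0.05. With each array centred on its median, the split was 214 higher and 266 lower. The windows were apart in every sample for all 554, and over all probe sets in 26.4%. For independent samples chance gives 10%, but neighbouring times of 1 culture are alike, so the share expected by chance here is not known. The total of 554 became 986 without the 0 h array, 108 without 2 h, 1739 without 4 h, 271 without 8 h, 179 without 10 h, 44 without 14 h, 1 without 16 h and 30 without 19 h. It was 172 without the filter, 245 without a mean trend, 266 with 6 h moved to the early window and 1073 with 12 h moved to the late window. Without the 0 h and 2 h arrays, chosen after seeing the data, 224 were higher and 147 lower, 129 of them among the 554. Of the 20 named calls, all 20 were lost without the 16 h array, 19 without 19 h, 18 without 14 h, 15 without 2 h, 14 without 10 h, 12 without 8 h, 5 without 12 h, 2 without 4 h (PORB and UNG), 2 without 6 h (PORB and ATMAP65-6) and 1 without 0 h (ATMAP65-6), with an adjusted p of 0.0518 to 0.173. In other alternatives 15 were lost without the filter (0.0763 to 0.140), 12 without a mean trend (0.0535 to 0.0689), 13 with 6 h moved (0.0517 to 0.257) and 11 without the 0 h and 2 h arrays (0.0564 to 0.239). Robust moderation ended 3 (0.0504 to 0.0567), a pseudocount 1, PORB (0.0552), and 12 h moved 1, XTH20 (0.0592). The differences were -0.73 for ATMND1 and -0.72 for HTB4 without the 0 h and 2 h arrays.

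**Figure D3:**
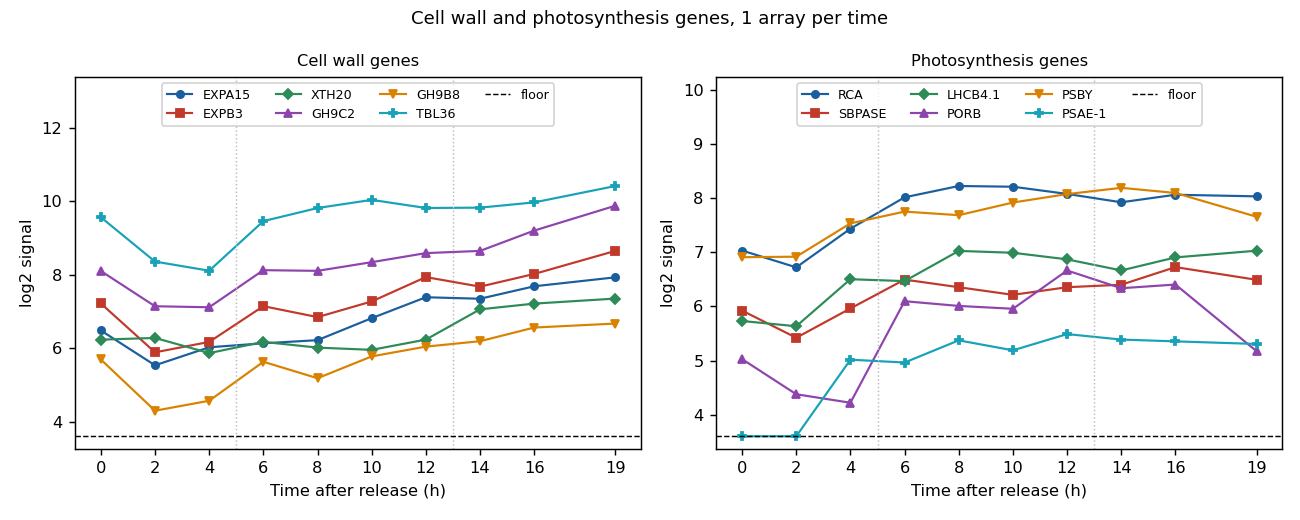
Log2 signal against time after release (h), 1 array per time, for 6 genes of cell wall proteins on the left and 6 photosynthesis genes on the right, with window borders dotted and the floor dashed. GH9C2 is at 138 at 4 h and 939.5 at 19 h in linear signal, and RCA at 105.5 at 2 h and 299 at 8 h.

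Core histones were lower at the late times, with 0 of 6 positive and a median of -0.997 (camera, adjusted p = 5.05e-06; adjusted p = 0.351 with an estimated correlation), 3 over all genes and 6 adjusted over the list alone. The ATG8 and ATG3 genes were lower by a median of -0.51 (adjusted p = 5.05e-06; adjusted p = 0.351 with an estimated correlation), with 0 of 9 positive and 3 called, ATG8D, APG8H and ATG8F. Photosynthesis markers were higher, with a median of 0.91, 2 over all genes, RCA and SBPASE, and 3 adjusted over the list alone (adjusted p = 0.00529; adjusted p = 0.351 with an estimated correlation). Their median was 0.57 without the 0 h and 2 h arrays. The nuclear photosynthesis genes were higher, with a median of 0.74 and 2 called, PSBY and PORB (adjusted p = 0.00604; adjusted p = 0.429 with an estimated correlation), lost without the 0 h and 2 h arrays (median 0.31, 0.329; 0.00111 to 0.429 over alternatives). Expansins and XTH enzymes were higher, with a median of 0.73, 9 of 9 positive and 3 called (adjusted p = 0.0105; adjusted p = 0.429 with an estimated correlation), lost without the 4 h array (0.117; 0.000157 to 0.429 over alternatives). Their median was 0.22 without the filter, 1.13 without 0 h and 1.34 without the 0 h and 2 h arrays. The G2 and mitosis list had a median of 1.74 and a mean of 1.03 but did not pass (adjusted p = 0.143), except without the 6 h array (0.0138) and with 6 h moved to the early window (0.00781; 0.00781 to 0.672 over alternatives). It had 2 called members, AT4G14330 up and HTR12 down, and 5 adjusted over the list alone.

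The plastid genome had a median of 0.19 over 68 probe sets with rpl22 and ndhG called (adjusted p = 0.121), and passed without the 0 h or 16 h array (0.0153 and 0.0260) and without the filter (0.0329; 0.0153 to 0.677 over alternatives). Its median was 0.12 without the 2 h array and with 6 h moved. Calcium and stress-induced regulators had a median of -0.06 (adjusted p = 0.180) and passed without the 4 h array (0.0289, median -0.52; 0.0289 to 0.807 over alternatives). Their median turned to 0.22 without the 2 h array, 0.07 without 19 h, 0.08 without the filter, 0.10 with 6 h moved and 0.29 without the 0 h and 2 h arrays, and did not pass there. The other lists did not pass (adjusted p 0.121 to 0.851). Medians, with their range over alternatives, were -0.03 for DNA replication (-0.13 to 0.08; 2 adjusted over the list alone), -0.59 for touch and wounding (0 adjusted over the list alone, 1 at an unadjusted p under 0.05; -1.19 without the 2 h array, -1.31 without 4 h and -0.99 without 14 h), -0.29 for replication and chromatin assembly (-0.42 to -0.13), -0.10 for DNA repair (-0.27 to 0.11) and 0.08 for RNA polymerase subunits (-0.21 to 0.27). The median difference of all tested probe sets was 0.0872 in this contrast, and camera's direction is relative to the other probe sets. Median, mean and camera's direction differed in sign for 5 lists that did not pass. All were down in camera, with median and mean of 0.0022 and 0.39 for mitosis and cytokinesis, 0.02 and 0.04 for tubulins, 0.01 and -0.01 for reference genes (0 adjusted over the list alone), -0.10 and 0.05 for UDP-glycosyltransferases and -0.01 and 0.06 for the mitochondrial list. Their medians ran over alternatives from -0.09 to 0.07, -0.16 to 0.15, -0.07 to 0.06, -0.28 to 0.14 and -0.15 to 0.09. The median turned direction in at least 1 alternative for these 5 lists and for DNA replication, DNA repair and RNA polymerase subunits.

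Between the middle and late windows no single gene passed. The genes with the lowest p were XTH20 with a difference of 1.11 (SE 0.15, adjusted p = 0.186), AUR3 with -0.86, AGL28, a MADS-box protein, with 1.45, scpl26 with -0.64 and CHR24, a chromatin remodeller, with -0.66. In limma 0 probe sets were higher and 0 lower, with 686 at an unadjusted p under 0.05. The windows were apart in 11.1% of probe sets, where chance gives 5.71% for independent samples, which neighbouring times are not.

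Some lists differed between these windows. Core histones were lower, with 0 of 6 positive, a median of -0.48 and 2 adjusted over the list alone (camera, adjusted p = 3.82e-05; adjusted p = 0.351 with an estimated correlation). Expansins and XTH enzymes were higher, with a median of 0.82 and 8 of 9 positive (adjusted p = 6.82e-05; adjusted p = 0.351 with an estimated correlation), and a median of 0.16 without the filter. The plastid genome was higher, with a median of 0.14 and 53 of 68 positive (adjusted p = 8.79e-05; adjusted p = 0.413 with an estimated correlation). Calcium and stress-induced regulators had a median of 0.45 with 11 of 12 positive (adjusted p = 0.0257; adjusted p = 0.429 with an estimated correlation). That was lost without the 0, 2, 14 or 16 h array (0.0599 to 0.124) and without the 0 h and 2 h arrays (0.0716; 0.00815 to 0.429 over alternatives), and the median was 0.29 without 8 h. The added mitosis and cytokinesis list was lower, with a median of -0.16 and 4 of 15 positive (adjusted p = 0.0462; adjusted p = 0.413 with an estimated correlation). It was lost without the 8, 10 or 19 h array (0.107 to 0.188) and with 12 h moved (0.107; 0.000111 to 0.413 over alternatives). Its median was -0.38 without 6 h, -0.35 with 6 h moved, -0.27 without 12 h or without 14 h and -0.09 without 10 h.

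The G2 and mitosis list was lower in the late than in the middle window, with a median of -0.21, 2 of 7 positive and 2 adjusted over the list alone (adjusted p = 0.0462; adjusted p = 0.565 with an estimated correlation). The direction of its median turned without the 10, 12 or 19 h array, to 0.04, 0.02 and 0.05 (0.190 to 0.458), and with 12 h moved to the late window, to 0.24 (0.684). The call was also lost without the 0, 2 or 4 h array (0.0640 to 0.0750), without a floor (0.0517), without the filter (0.0515), with quantile normalization (0.0548) and without the 0 h and 2 h arrays (0.123; 2.71e-06 to 0.684 over alternatives). The median was -0.65 without 6 h and with 6 h moved, and -0.42 without 14 h.

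The remaining lists did not pass. Tubulins had a median of -0.17 (adjusted p = 0.0764) and passed without the 2, 6 or 14 h array (0.0240 to 0.0474), with 6 h moved (0.0232) and without the 0 h and 2 h arrays (0.0495; 0.0232 to 0.744 over alternatives). Their median was -0.11 without the 12 h array, -0.08 without 16 h, -0.09 without 19 h and -0.02 with 12 h moved. The ATG8 and ATG3 genes had a median of -0.10 (adjusted p = 0.0764) and passed without the 12 or 19 h array (0.0116 and 0.0401), without the filter (0.0340) and with 12 h moved (0.00363; 0.00363 to 0.565 over alternatives). Their median was -0.17 without the 12 h array and -0.18 with 12 h moved, but -0.05 without 8 h and -0.07 without 14 h or without 16 h. Medians, with their range over alternatives, were 0.21 for DNA replication (0.06 with 12 h moved to 0.26; 0.13 without 19 h), 0.15 for touch and wounding (0.06 without 8 h to 0.38 without 19 h), 0.03 for photosynthesis markers (-0.10 to 0.13), -0.02 for reference genes (-0.17 to 0.01; mean 0.01, camera's direction down), 0.09 for replication and chromatin assembly (-0.03 to 0.22), -0.07 for DNA repair (-0.11 to 0.05), -0.15 for UDP-glycosyltransferases (-0.25 to 0.03), -0.09 for RNA polymerase subunits (-0.13 to -0.02), -0.13 for the mitochondrial list (-0.16 to -0.05) and 0.08 for nuclear photosynthesis genes (0.02 without 16 h to 0.17 with 12 h moved; 0.15 without 19 h). Their adjusted p ran from 0.143 to 0.992. The median turned direction in at least 1 alternative for photosynthesis markers, reference genes, replication and chromatin assembly, DNA repair and UDP-glycosyltransferases. Of the lists fixed beforehand among these, 0 members passed adjusted over the list alone, and 0 had an unadjusted p under 0.05.

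All 3 touch and wounding genes were lower at 2 h than in the 0 h sample, taken at the end of the wash. Their log2 differences ran from -3.59 to -0.98, with 1 array on each side and no test. STZ, a zinc finger repressor induced by stress, had a signal of 579 at 0 h and 87.9 at 2 h, and WRKY53 134 and 67.9. The 5 lowest named genes were XTH19 (log2 difference -3.61, at the floor at 2 h), CML38, a calmodulin-like protein (-3.59, at the floor at 2 h), CML23 (-2.73), STZ (-2.72) and atpB, the plastid ATP synthase subunit (-2.67). BGLU27, a beta-glucosidase (5.55, at the floor at 0 h), pEARLI4 (4.37), GTR2, a glucosinolate transporter (4.12), MT1C, a metallothionein (3.57, at the floor at 0 h), and HCT, an enzyme of phenylpropanoid synthesis (3.39), were the 5 highest, and HCT reached 2133 at 2 h. BGLU27 stood at 568.5 at 2 h and 33.8 at 4 h. Differences from the floor are lower bounds of their size.

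By list, the 3 touch and wounding genes had a median difference of -2.72, below all 10000 matched random lists (percentile 0). The percentiles ignore correlation within a list, estimated in camera at 0.79 for these genes and 0.70 for core histones. Correlated lists can reach extreme percentiles more readily than random ones. Expansins and XTH enzymes had -0.95 (0.02), tubulins -0.48 (1.18) and the plastid genome -0.23 (0.69). Core histones were 0.67 higher at 2 h with 6 of 6 positive (99.9), and UDP-glycosyltransferases 0.55 higher with 9 of 11 positive (99.97). Without the filter the medians of the expansins and of the UDP-glycosyltransferases were 0. The other lists lay between the 5th and 93rd percentiles: 0.35 for DNA replication (92.3), -0.17 for G2 and mitosis (37.5), -0.31 for photosynthesis markers (25.5), -0.06 for reference genes (48.2), -0.04 for replication and chromatin assembly (53.1), 0.07 for mitosis and cytokinesis (86.4), -0.41 for DNA repair (5.06), -0.02 for calcium and stress-induced regulators (66.3, with 6 of 12 positive), -0.22 for ATG8 and ATG3 (18.5), -0.04 for RNA polymerase subunits (53.4), 0.12 for the mitochondrial list (81.8) and -0.09 for nuclear photosynthesis genes (50.4). With quantile normalization the median turned to 0.03 for replication and chromatin assembly, 0.09 for calcium and stress-induced regulators and 0.0022 for nuclear photosynthesis genes. Over all probe sets, 589 were over 2-fold higher and 951 over 2-fold lower at 2 h.

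**Figure D4:**
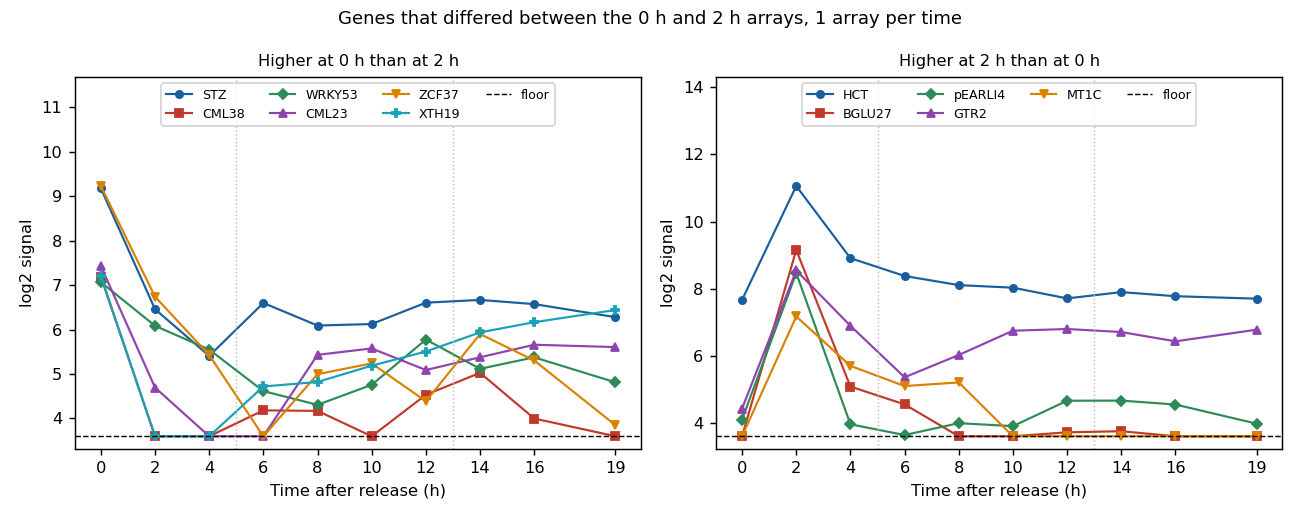
Log2 signal against time after release (h), 1 array per time, for 6 genes higher at 0 h than at 2 h on the left and 5 genes higher at 2 h than at 0 h on the right, with window borders dotted and the floor dashed. STZ is at 579 at 0 h and 87.9 at 2 h in linear signal, and HCT at 203 and 2133.

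Between 16 h and 19 h the arrays differed less, again without a test. The 5 highest differences of named genes were those of SEC5B, an exocyst subunit (1.14), PID2, a protein kinase (1.11), BIM1, a transcription factor (0.99), RALFL31, a signalling peptide (0.98), and DER2.1, a Derlin-like protein (0.90). The 5 lowest were those of ZCF37 (-1.46), PORB (-1.23), SDH1-2, a succinate dehydrogenase subunit (-1.21, at the floor at 19 h, or -2.57 without a floor), CYP51G2 (-1.18) and ATPP2-B3 (-1.16). Core histones were higher at 19 h with 6 of 6 positive and a median of 0.32 (percentile 99.85), and the plastid genome with a median of 0.16 and 41 of 68 positive (100). The G2 and mitosis list was lower, with a median of -0.45 and 1 of 7 positive (2.02), or -0.24 with quantile normalization. These percentiles, too, ignore correlation between the genes of a list.

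Other lists at this step had medians of -0.17 for DNA replication (13.1), -0.40 for touch and wounding (14.7), -0.03 for photosynthesis markers (47.6), 0.14 for reference genes (84.1), 0.14 for replication and chromatin assembly (88.2), -0.07 for mitosis and cytokinesis (36.8), 0.11 for DNA repair (97.2), 0.02 for tubulins (38.7), 0.14 for expansins and XTH enzymes (94.2), -0.29 for calcium and stress-induced regulators (5.99), -0.32 for UDP-glycosyltransferases (8.22), 0.11 for ATG8 and ATG3 (89.8), -0.03 for RNA polymerase subunits (18.9), 0.06 for the mitochondrial list (54.1) and -0.33 for nuclear photosynthesis genes (8.75). With quantile normalization the median turned to 0.02 for mitosis and cytokinesis, -0.03 for tubulins and -0.05 for the mitochondrial list. Over all probe sets, 76 were over 2-fold higher and 166 over 2-fold lower at 19 h. With quantile normalization these were 124 and 74, and without the filter 151 and 510.

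Array quality was read from the control probe sets and from the arrays' likeness to each other. The 3' to 5' signal ratio of actin ranged from 2.16 at 6 h to 4.25 at 8 h, that of GAPDH from 1.00 at 14 h to 1.32 at 8 h and that of ubiquitin from 2.79 at 2 h to 3.67 at 0 h. The mean correlation with the other 9 arrays was 0.864 at 2 h and 0.912 at 0 h, and between 0.926 and 0.946 at the other times. Probe sets over 2-fold apart between neighbouring arrays numbered 1540 from 0 h to 2 h and 1634 from 2 h to 4 h, then 586, 571, 296, 226, 189, 164 and 242 over the later steps.

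**Figure D5:**
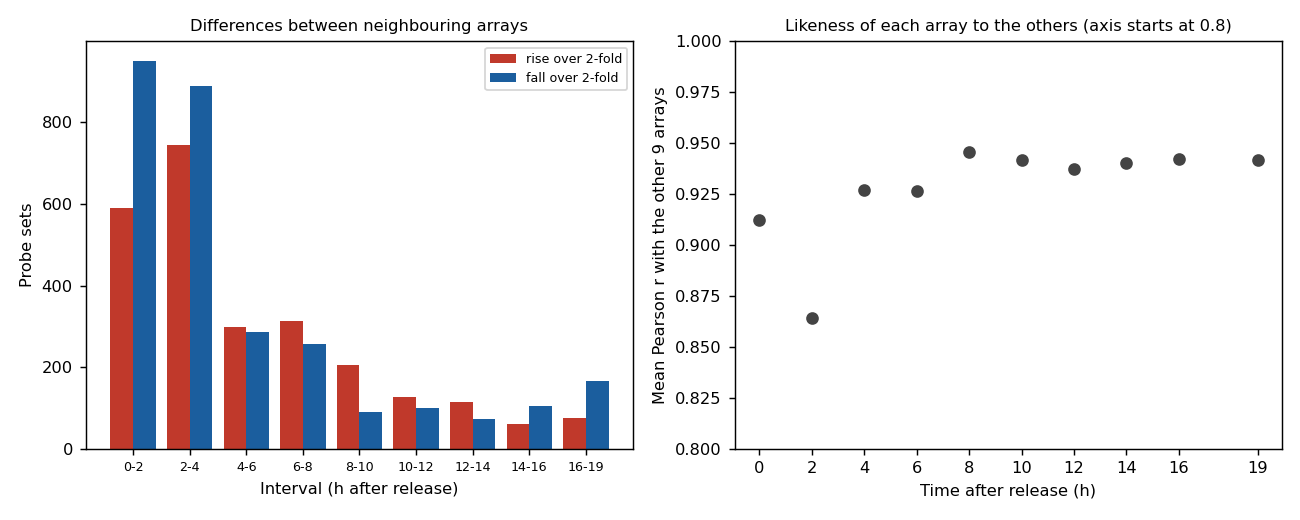
Left, the number of probe sets over 2-fold higher or lower between each array and the next, against the interval (h). Right, each array's mean Pearson correlation with the other 9 arrays, with an axis that starts at 0.8, which is lowest at 2 h with 0.864.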

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

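The tests of degraded RNA, of array scaling and of handling in the wash were chosen only after the result was seen. Of 7 measures of array quality tested, 1 set an array apart: the mean correlation of the 2 h array with the other 9 was 0.864 and the next lowest, at 0 h, 0.912, a gap of 0.586 of the whole range, above Dixon's 95% critical value for 10 samples. Chance passes this critical value in about 1 in 20 groups of independent values for a single measure, and more often for at least 1 of 7 measures. The mean correlations share pairs of arrays and come from 1 ordered course. They are not independent, so this rate need not hold for them.

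For the 2 h array, degraded RNA is argued against by 2 of the 3 control genes, whose 3' to 5' ratios lay at or below the median of the other arrays: ubiquitin, the lowest of all at 2.79, and actin at 2.97, while GAPDH at 1.26 was the second highest. Independent noise of single probe sets is argued against by 86 genes with a pair of probe sets. Their 2 h deviations, taken from the mean of 0 h and 4 h, correlated across genes with r = 0.734 (95% bootstrap interval 0.624 to 0.829). The highest of 100 random pairings gave 0.301 and the same measure at 10 h gave -0.0127. Differences of the 0 h array enter this measure too. A hybridisation or labelling fault that moved both probe sets of a gene alike would also give such a correlation, so it stays open. A state of the culture that lasted to 4 h was not excluded: deviations at 2 h and at 4 h, each from different later arrays, correlated across genes with r = 0.404. Those at 2 h and at 0 h did so with r = 0.456, so the likeness is not particular to 2 h and 4 h and does not single out such a state. The differences of 2 h minus 8 h and of 6 h minus 10 h, for comparison, correlated with r = 0.0959, and genes are not independent replicates. How the single 2 h sample was handled stays open, since no second sample of this time was analysed here.

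The touch and wounding genes were lower at 2 h than at 0 h. The median difference of all tested probe sets was -0.0772 where the list's was -2.72, so the list was lower relative to most other probe sets. The common scaling of the arrays itself brings the median of all near 0, so this value decides nothing further about scaling. Whether handling during the wash or the release itself lies behind the list's difference of -2.72 cannot be told apart, because no unwashed sample and no washed sample without aphidicolin was analysed here.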

How the results depend on the processing

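The fits without the 0 h and 2 h arrays were chosen only after the result was seen. No paired analysis was possible because the times share only replicate number 1. Late against middle had 0 calls in limma under every alternative run, which shows no stability, since the count at an unadjusted p under 0.05 was 686 and ranged from 409 (without 16 h) to 1445 (without the 0 h and 2 h arrays). Both counts of the first interval stayed within 1.5 times under every alternative run, and the time course did so without a floor, with a pseudocount, under both other scalings, with robust moderation, at the 60th percentile filter and with 3 or 5 spline terms. For the results that follow, the cause was not tested, except that the counts without the filter come from more probe sets tested (22746).

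Without the filter, the time course gave 281 calls, middle against early 0 higher and 0 lower (limma; 3287 at an unadjusted p under 0.05), late against early 85 higher and 87 lower, and the last interval 151 higher and 510 lower by over 2-fold. Without a mean trend in eBayes, these were 462 for the time course, 25 and 46 for middle against early and 135 and 110 for late against early. The 60th percentile filter gave 144 higher for middle against early, and quantile normalization 124 higher and 74 lower for the last interval. With 6 h moved to the early window, middle against early gave 115 higher and 37 lower and late against early 150 and 116. With 12 h moved to the late window, they gave 18 and 34, and 639 and 434. Without the 0 h and 2 h arrays, the time course gave 1231, middle against early 37 lower and late against early 147 lower. List calls in camera were counted separately for each list in each window contrast, so they are counts of tests and not of lists. Estimated correlations gave 0 such calls, against 18 over all lists and 7 over the fixed lists with the preset one.

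Leaving out 1 array at a time, counts ranged from 236 (without 12 h) to 2901 (without 0 h) for the time course, 0 (without 8, 10 or 12 h) to 1125 (without 4 h) higher and 0 (without 8 or 10 h) to 738 (without 4 h) lower for middle against early, and 0 to 1044 higher and 1 to 695 lower (without 16 h and 4 h) for late against early. List calls, again counted for each list in each window contrast, ranged from 15 to 20 over all lists and 6 to 8 over the fixed ones. The median of the G2 and mitosis list, late against middle, ranged from -0.65 (without 6 h) to 0.0486 (without 19 h), positive also without 10 h, 0.04, and 12 h, 0.02, and with 12 h moved to the late window, 0.24. For genes named in window contrasts, leaving out 1 array ended the call in 189 fits, and other alternatives fixed beforehand in 98, none with a change of direction. Low signal limits genes near the floor: 0.585% of the values tested lay there, and differences of such genes are bounds.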

Other observations

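The courses used here were chosen only after the result was seen, as were the tests of genes that follow them. With a correlation over 0.95 across the 10 times, 12 probe sets followed the mean course of the 3 Aurora kinases, which was lowest at 4 h and highest at 10 h. Of these, 7 had no gene listed, and ZCF125 was the single one with a symbol (r = 0.960). In 99 shuffled orders of that course the highest count was 2. The mean course of the 6 core histone probe sets, highest at 2 h and lowest at 14 h, was followed by 22 probe sets, of which 3 had a symbol: APA1, an aspartic protease (r = 0.977), FANCM (0.964) and CHI (0.960). In 99 shuffled orders the highest count there was 3. Shuffled orders also break the likeness of neighbouring times, so they are no measure of how many probe sets follow any smooth course by chance, which was not tested. These are correlations of single courses and show no shared regulation.

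Orders and splits of the samples were counted as planned. Of 100 orders of the 10 times, the real one included, 3 called at least as many probe sets as the real 760, a share under 0.05. The highest of the others called 1157, more than the real order. Random orders break the likeness of neighbouring times, so any smooth series would exceed most of them. The count therefore does not exclude chance. Of 100 splits into windows, 1, the real one, reached its 154 calls for middle against early (highest other 71), and 1 its 554 for late against early (highest other 96). The real windows are runs of neighbouring times, while the other splits mix distant times. Any smooth drift of the 1 culture would favour the real windows, so these counts do not exclude chance. For late against middle, with 0 calls in limma (686 at an unadjusted p under 0.05), all 100 splits reach as many whatever their calls, and the highest other called 1, so this count says nothing about chance.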
